A study of Drosophila melanogaster with 6 samples.

How the data were processed

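Whole adult Drosophila melanogaster females of 2 genotypes were profiled on 6 one-colour Affymetrix arrays, 3 per genotype. Calment1/4 is a mutant that had been isogenized into a stock called CS10, and CanS is the wild-type comparison stock. Flies were cultured at 25 °C, each sample pooled 30 to 35 frozen flies, and total RNA was extracted with TRI-Reagent and turned into biotin-labelled cRNA, per the labels' protocols. The titles call the arrays biological replicates, and the replicate number comes from the title. Genotype and stock background change together between the groups, so every difference below is between the 2 stocks.

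The deposited values are log2 expression summaries, 1 per probe set and array, on a scale shared by the 6 arrays. The submitters' processing notes name affy 1.36.0, RMA and MAS5 without saying what each was used for, and the step that made the deposited log2 values is not given in the sources used here. RMA-type summaries are normalized between arrays, so a change shared by most transcripts of a sample would not be seen in them, and dim probe sets are pulled towards a common floor, which makes folds against the floor depend on it. Medians of the arrays lay between 5.84 and 5.91, and their 10th percentiles between 3.43 and 3.49. Scanner files and detection calls were not used here, so whether a dim probe set stood above background was not judged.

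The table holds 18952 probe sets. The 183 AFFX control probe sets were left out of the tests, which leaves 18769. Gene names came from a table of the platform's annotation, updated through gene identifiers to the RefSeq annotation of the assembly Release 6 plus ISO1 MT. Exactly 1 gene symbol was held by 13647 probe sets, several by 402 and none by 4720. Of the probe sets with 1 symbol, 13544 matched RefSeq and 103 kept the platform's name. They stand for 11982 genes, of which 1094 have over 1 probe set. RefSeq also gave the chromosome arm and the order of genes. The annotation build of the array is not stated, so no coordinates are given.

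No name or synonym in either table is Calment, so the gene that the mutation affects is not named here and has no value, and the genotype labels were not checked through it.

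The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term) and Benjamini-Hochberg adjustment over the 18769 probe sets, with a threshold of 0.05. Changes of at least 2-fold were also counted. For 29 gene lists the test was camera with a preset inter-gene correlation of 0.01, on the brightest probe set of each gene, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. Changed genes were counted per chromosome arm with Fisher's exact test, two-sided, adjusted over 6 arms. Genes are not independent replicates in the arm test.

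The named genes are the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, taken from probe sets with exactly 1 symbol, with the probe set of smallest p for a gene that has several. From each list up to 2 rises and 2 falls past the threshold are added, or the 2 members of smallest p where none passed. The lists, the tests, this rule and most alternatives were fixed before the data were examined. The alternatives were a repeated quantile normalization, centring on medians, a filter on the dimmest 33.3% of probe sets, eBayes with trend and robust on, array weights, the replicate number as a block, a stricter threshold, 1 probe set per gene, and leaving out each array in turn. An ovary covariate, made from the median of the female germline list on each array, and leaving out 2 arrays together were added after seeing the data. A pseudocount did not apply, since the values were already on a log scale.

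The steps were tested on simulated data. In 20 simulations of this comparison over 18769 probe sets, 200 of them changed, the limma step recovered 39.3% of changes of 0.5 on the log2 scale, 86.7% of changes of 1 and 98.9% of changes of 2, and 4.64% of its calls were false. A shift of 0.3 given to 1 gene list, the glutathione S-transferases, was found in 10 of 10 simulations, with 0.3 other lists called per simulation. In the real data no list median with all 6 arrays was as large (largest in size -0.27). How often such smaller shifts would be found was not simulated. The simulated noise was independent between probe sets. These rates therefore do not cover genes that vary together between arrays, as members of a list can. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9.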

Results

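The data are 6 arrays of whole adult females, 3 of the mutant Calment1/4 and 3 of the wild-type stock CanS (Canton-S). The series' title places the mutant in the study of longevity and resistance to oxidative stress, and the comparison asks which transcripts differ between the mutant and the wild-type stock. The arrays correlated with each other at 0.991 to 0.998 over all tested probe sets. Calment1/4 replicates 2 and 3 were the closest pair (r = 0.998), while Calment1/4 replicate 1 correlated best with CanS replicate 3 (r = 0.995). These 2 arrays also had the lowest yolk and eggshell medians of their groups, 0.80 and 0.63 below their group mates on the log2 scale, and their gut marker medians lay 0.40 and 0.28 above. The mean log2 difference between 3' and 5' probe sets of Act5C, a measure of RNA integrity, was 3.46 in these 2 arrays and 3.63 in the other 4.

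The largest differences between the stocks were genes close to the array floor in one stock and bright in the other. CG43090 had a mean log2 value of 12.75 ± 0.10 in Calment1/4 and 3.21 ± 0.09 in CanS (SD, n = 3 each), percentile ranks of 98.98 and 4.71 among all probe sets. Arts stood at 10.18 ± 0.05 against 3.85 ± 0.13. CG3036 showed the opposite pattern, 3.92 ± 0.26 in Calment1/4 and 10.04 ± 0.15 in CanS. Cytochrome P450 genes changed in both directions, with Cyp6a17 and Cyp6w1 higher in Calment1/4 and Cyp4d21 lower, and fit, which encodes a secreted protein of the female fat body, fell by 2.17 on the log2 scale.

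In all, 87 of 18769 probe sets passed an adjusted p of 0.05 in limma, 50 higher and 37 lower in Calment1/4, which is 0.464% of those tested. At least 2-fold changes were found for 38, of which 25 were higher and 13 lower. The probe sets with exactly 1 symbol stand for 67 genes, 35 higher and 32 lower. Another 5 of the 87 have several symbols and 15 have none, 12 of them higher and 3 lower. In each of the 87 the 3 Calment1/4 arrays lay on one side of the 3 CanS arrays. Groups did not overlap in 2370 of all tested probe sets, or 12.6%, where chance gives 10%. An unadjusted p under 0.05 was reached by 1440 probe sets, where 938 would be expected by chance.

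Among the 12 largest rises, CG43090 differed by 9.54 on the log2 scale (SE 0.09, adjusted p = 4.11e-10 in limma) and Arts by 6.33 (SE 0.09, adjusted p = 7.50e-09). A probe set shared by Apl and Arts rose by 4.24. CG31955 rose 6.44-fold, from a mean of 4.55 in CanS (percentile rank 34.4), and Cyp6a17, a cytochrome P450, 6.02-fold, from 3.80 (percentile rank 18.05). The pigmentation gene y (yellow) was 4.01-fold higher (adjusted p = 0.00892 in limma), and lectin-24A, a C-type lectin, was 3.87-fold higher, from 3.59 in CanS (percentile rank 12.8). The folds of CG43090, Arts, Cyp6a17 and lectin-24A rest on CanS values close to the floor and depend on it. Rbm13 rose by 1.77, CG10927 by 1.68, CG46491 by 1.63, Cyp6w1 by 1.27, phu by 1.26 and CG16704 by 1.18 on the log2 scale.

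Among the 12 largest falls, CG3036 differed by -6.12 on the log2 scale (SE 0.14, adjusted p = 1.84e-07 in limma). The log2 difference was -2.17 for fit (SE 0.28, adjusted p = 0.0180 in limma) and -2.09 for Cyp4d21, a sex-specific cytochrome P450. CG3036 and Cyp4d21 were dim in Calment1/4, with means of 3.92 (percentile rank 21.2) and 4.33 (percentile rank 30.4). The sizes of their falls can therefore depend on the floor. CG12998 differed by -1.58 and narya, a gene of meiotic recombination, by -1.48. Ugt36A1, a UDP-glycosyltransferase, was at -1.40, and Ser12, a serine protease, at -1.25. Sr-CI, a scavenger receptor of blood cells, was at -1.24, the cuticle protein gene Cpr92F at -1.13 and CG9664 at -1.03. CG30083 and the zinc transporter Zip102B, at -0.99 and -0.98, lay just under a 2-fold change.

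**Figure D1:**
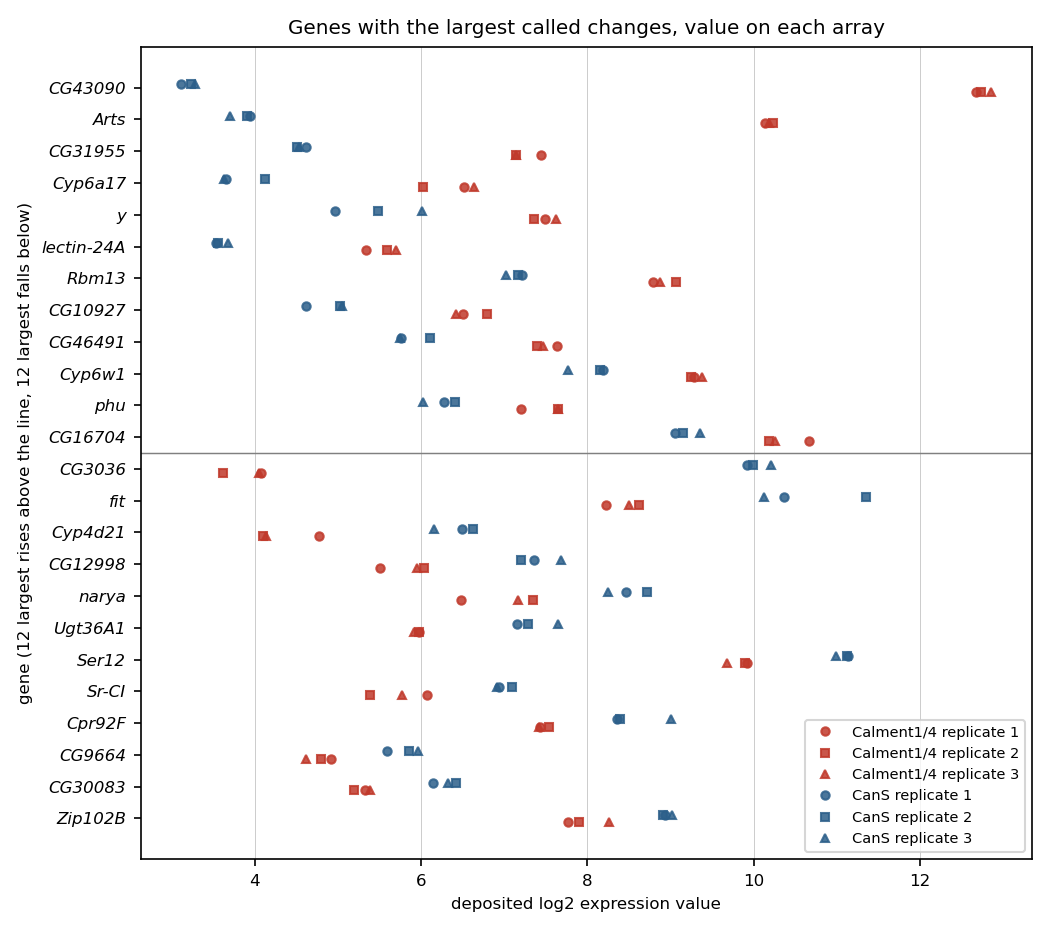
Deposited log2 value (horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls in Calment1/4, 1 point per array, with colour for the stock and shape for the replicate. In every gene the 3 Calment1/4 arrays lie apart from the 3 CanS arrays, as the rule that chose the genes required. CG43090, at 12.75 against 3.21 on average, has the widest gap.

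The number of calls depended on single arrays. It was 281 without Calment1/4 replicate 1, 38 without Calment1/4 replicate 2, 45 without Calment1/4 replicate 3 and 54 without CanS replicate 3, and 228 without Calment1/4 replicate 1 and CanS replicate 3, while the at least 2-fold count was 94 without Calment1/4 replicate 1 and 96 without both. Of the 87 calls 35 held with each of the 6 arrays left out in turn and 52 were lost at least once. The call of fit was lost without Calment1/4 replicate 2 (-2.25, adjusted p = 0.0829), Calment1/4 replicate 3 (-2.19, adjusted p = 0.0746) and CanS replicate 1 (-2.29, adjusted p = 0.0567). With all 6 arrays, eBayes with trend and robust on also ended the call of fit (-2.17, adjusted p = 0.0714). That of phu was lost without Calment1/4 replicate 2 (1.19, adjusted p = 0.0747), Calment1/4 replicate 3 (1.19, adjusted p = 0.0501) and CanS replicate 1 (1.28, adjusted p = 0.0550), and that of CG16704 without CanS replicates 1 (1.11, adjusted p = 0.0567) and 2 (1.16, adjusted p = 0.0607). For narya each array but Calment1/4 replicate 1 ended the call (-1.65 to -1.36, adjusted p up to 0.124). For Sr-CI each array but Calment1/4 replicates 1 and 2 did so (-1.27 to -1.18, adjusted p up to 0.0894), for Cpr92F each but Calment1/4 replicate 1 and CanS replicate 3 (-1.24 to -1.10, adjusted p up to 0.137), and for Zip102B each but Calment1/4 replicates 1 and 3 (-1.002 to -0.94, adjusted p up to 0.109). CG9664 lost its call without Calment1/4 replicate 2 (-1.04, adjusted p = 0.0732) and CanS replicate 2 (-1.003, adjusted p = 0.0560). Without Calment1/4 replicate 1, calls were gained by TotC (-2.97), tobi (-2.29), Obp83cd (-0.94), BomBc2 (-0.73), eater (-0.71), Hsp68 (-0.59) and AkhR (0.48), and without CanS replicate 1 by Lsp2 (-1.75) and Npc2e (-0.98).

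Gene lists fixed beforehand were then compared, to ask whether groups tied to stress resistance, immunity, metabolism and reproduction moved as a whole. With the preset correlation 10 of 29 lists passed, 3 upwards and 7 downwards. After repeated quantile normalization 8 did, 1 upwards and 7 downwards, and with an estimated correlation none did (limma's camera, lowest adjusted p = 0.657, with 0 lists at an unadjusted p under 0.05). The rotation test fry, read for a shift in 1 direction, also passed 0 lists (lowest adjusted p = 0.322). At an unadjusted p under 0.05 it had 2 lists. Fry's mixed test asks instead whether members changed in either direction. Its unadjusted p ran from 6.78e-08 (lipid genes) to 0.865 (DNA damage and cell death). It was 4.05e-06 for antioxidant enzymes, 0.000106 for cytochrome P450s and 0.000139 for the insulin, TOR and adipokinetic list. The mixed p were not adjusted over the lists. Below, members said to have risen or fallen passed the threshold over all 18769 probe sets, and counts adjusted over the list alone follow where they differ.

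Of 24 antioxidant enzymes measured, 1 rose, Prx6c, a peroxiredoxin with close copies in the genome (2.25-fold, adjusted p = 0.00892 in limma), and 23 did not pass. The list's median was 0.02 on the log2 scale (adjusted p = 0.269). A probe set shared by Gss1 and Gss2, glutathione synthetase genes, differed by -0.78 and passed, but not without Calment1/4 replicates 2 or 3 or CanS replicates 2 or 3 (adjusted p up to 0.104). The 34 glutathione S-transferases shifted down with a median of -0.05 (adjusted p = 0.00156 preset, adjusted p = 0.657 with an estimated correlation), and -0.08 without Calment1/4 replicate 2 or without CanS replicate 1. One of them, GstD5, fell by 0.91 and 33 did not pass; 2 fell adjusted over the list alone. The call of GstD5 was lost without each array but Calment1/4 replicate 1 and CanS replicate 2 (-0.98 to -0.79, adjusted p up to 0.132). Among 81 cytochrome P450s 3 rose, Cyp6a17, Cyp6w1 and Cyp6a2, the last named after its values were seen, and 1 fell, Cyp4d21. Cyp6a2 lost its call without each array but Calment1/4 replicate 1 and CanS replicate 3 (adjusted p up to 0.113). Adjusted over the list alone 4 rose and 4 fell, and the list as a whole did not pass (median -0.03, adjusted p = 0.375), although without Calment1/4 replicate 1 it did (median -0.06, adjusted p = 0.0202), as it did with array weights (adjusted p = 0.0479). Of 35 UDP-glycosyltransferases only Ugt36A1 passed, and the list's adjusted p was 0.0699 with a median of -0.06. That list passed without Calment1/4 replicate 1 (median -0.12, adjusted p = 0.000455) and without CanS replicate 1 (median -0.10, adjusted p = 0.00704), and also with the filter on dim probe sets (adjusted p = 0.0492), with array weights (adjusted p = 0.00136) and without Calment1/4 replicate 1 and CanS replicate 3 (adjusted p = 0.00496). None of 14 heat shock proteins and chaperones passed. Hsp68 was at -0.46 (adjusted p = 0.250 in limma) and Hsc70-1 at 0.22, and the list's median of 0.02 and mean of -0.04 differed in sign, with camera's direction down (adjusted p = 0.687).

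Both immune lists shifted down with the preset correlation, but not on every array. The 19 antimicrobial and immune peptides had a median of -0.24 (adjusted p = 0.000760 preset, adjusted p = 0.657 with an estimated correlation), with 17 of 19 below 0 and none past the threshold. BomBc2 was at -0.54 and CecB at -0.26. The median was -0.09 without Calment1/4 replicate 2 (adjusted p = 0.138) and -0.16 without CanS replicate 3 (adjusted p = 0.0812), and both end the call. Among 25 immune recognition and effector genes Tep3, a thioester-containing protein, fell by 0.48 and 24 did not pass, while 5 fell adjusted over the list alone. The call of Tep3 held with Calment1/4 replicate 1 left out and was lost without each other array (-0.51 to -0.44, adjusted p up to 0.250). That list's median was -0.16 (adjusted p = 0.000600 preset, adjusted p = 0.657 with an estimated correlation), -0.29 without Calment1/4 replicate 1 and -0.07 without Calment1/4 replicate 3. Around each gene's mean, Calment1/4 replicate 1 stood at 0.11 on the peptide list and 0.12 on the recognition list, above CanS replicates 1 and 2 (0.01 and 0.01, then 0.02 and 0.01). CanS replicate 3 was the highest array on both (0.27 and 0.26). The 5 Turandot stress peptides measured did not pass (median -0.02, adjusted p = 0.360). TotC was at -2.12 with an SE of 0.73 and overlapping groups, and TotZ at -0.08.

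Of 22 yolk and eggshell genes Cp18, a chorion protein, rose by 0.74 and 21 did not pass, with 2 rising adjusted over the list alone. The call of Cp18 was lost without each array but Calment1/4 replicate 1 and CanS replicate 1 (0.65 to 0.79, adjusted p up to 0.221). The list's median was 0.15 (adjusted p = 0.0368 preset, adjusted p = 0.759 with an estimated correlation). This call was lost after repeated quantile normalization (adjusted p = 0.0662), with the filter on dim probe sets (adjusted p = 0.0560), with the ovary covariate (median 0.04, adjusted p = 0.434) and without Calment1/4 replicate 1 and CanS replicate 3 (adjusted p = 0.0930). On this list the arrays of one group differed more than the groups did, from -0.39 to 0.35 in Calment1/4 and from -0.66 to 0.29 in CanS around each gene's mean. Its median was 0.44 without Calment1/4 replicate 1, 0.34 without CanS replicate 1, 0.24 without CanS replicate 2, 0.0012 without Calment1/4 replicate 2 (adjusted p = 0.356), 0.02 without Calment1/4 replicate 3 (adjusted p = 0.264) and -0.02 without CanS replicate 3 (adjusted p = 0.905). The 27 female germline genes, with bam at 0.33 and osk at 0.23, had a median of 0.06 and none passed (adjusted p = 0.157). As a list they passed without Calment1/4 replicate 1 (median 0.19, adjusted p = 3.10e-05), without CanS replicate 1 (median 0.11, adjusted p = 0.0499) and without CanS replicate 2 (median 0.09, adjusted p = 0.0266), and also with array weights (adjusted p = 0.00257) and without Calment1/4 replicate 1 and CanS replicate 3 (adjusted p = 0.00242). None of 31 testis and male accessory gland markers passed (median -0.01, adjusted p = 0.375), with Mst84Dd at -0.17 and Mst57Dc at 0.16.

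The carbohydrate metabolism, digestive protease and gut marker lists shifted down with the preset correlation, with no single member past the threshold. As fixed beforehand, the carbohydrate list names genes of glycolysis and glycogen beside those of sugar digestion. The gut list names amylase and trypsin genes that the other lists also name, so the lists are not independent. The 31 carbohydrate metabolism genes had a median of -0.11 (adjusted p = 0.00116 preset, adjusted p = 0.657 with an estimated correlation). The alpha-glucosidase gene tobi, which responds to insulin signalling, was at -1.98 (adjusted p = 0.0853 in limma) and Amyrel, an amylase-related gene, at -0.53. Adjusted over the list alone 3 fell, and the list's median was -0.17 without Calment1/4 replicate 1, -0.04 without Calment1/4 replicate 3 and -0.05 without CanS replicate 3, which ends the call (adjusted p = 0.150). The 27 digestive proteases had a median of -0.18 and 24 of 27 below 0 (adjusted p = 0.000600 preset, adjusted p = 0.657 with an estimated correlation), with Jon66Ci at -0.97 and Jon25Bi at -0.27. Their median was -0.11 without Calment1/4 replicate 2, -0.09 without Calment1/4 replicate 3 and -0.12 without CanS replicate 3. The 12 gut markers had a median of -0.23 (adjusted p = 0.00156 preset, adjusted p = 0.657 with an estimated correlation), and 3 fell adjusted over the list alone. Npc2e was at -1.31 and Npc2f at -0.40. Their median was -0.39 without Calment1/4 replicate 1 and -0.12 without Calment1/4 replicate 3. Around each gene's mean, Calment1/4 replicate 1 stood at 0.15 on both the carbohydrate and the gut list, above CanS replicates 1 and 2, and CanS replicate 3 was the highest array on both (0.20 and 0.30).

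The 23 insulin, TOR and adipokinetic signalling genes did not pass (adjusted p = 0.164). Their median was 0.03 and their mean -0.02, with camera's direction up, and adjusted over the list alone 3 rose and 2 fell. AkhR, the receptor of adipokinetic hormone, was at 0.56 (adjusted p = 0.0608 in limma). The 21 JNK pathway and longevity genes had a median of 0.04 (adjusted p = 0.319), with hep at 0.22 and p53 at 0.14. The 31 lipid genes had a median of 0.03 (adjusted p = 0.269), with Fad2 at 0.39 and FASN2 at 0.37, and 3 rose adjusted over the list alone. None of 72 respiratory chain genes passed, and the list stood at -0.04 (adjusted p = 0.0558), with ND-51L1 at -0.30 and UQCR-11L at 0.21. The list passed without Calment1/4 replicate 1 (median -0.12, adjusted p = 3.22e-05), without CanS replicate 1 (median -0.05, adjusted p = 0.0191) and without CanS replicate 2 (median -0.08, adjusted p = 0.00189). It also passed with the filter on dim probe sets (adjusted p = 0.0232), with trend and robust on (adjusted p = 0.0280), with array weights (adjusted p = 0.00257), with the mean of a gene's probe sets (adjusted p = 0.0447) and without Calment1/4 replicate 1 and CanS replicate 3 (adjusted p = 0.0223).

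The 34 cytosolic ribosomal proteins (median 0.03, adjusted p = 0.0922), the 69 mitochondrial ones (median 0.02, adjusted p = 0.375) and the 40 proteasome subunits (median 0.02, adjusted p = 0.687) had no member past the threshold. The cytosolic ribosomal list passed with trend and robust on (adjusted p = 0.0165), and the mitochondrial one without CanS replicate 2 (median 0.05, adjusted p = 0.0131). Among these genes RpS19b was at 0.24, RpL17 at 0.13, mRpS28 at 0.29, mRpL24 at 0.14, Prosbeta4R2 at -0.23 and Prosalpha6 at 0.22. A probe set shared by Prosalpha1 and Prosalpha1R rose by 0.66, a call that held with Calment1/4 replicate 1 left out and was lost without each other array (adjusted p up to 0.209). None of 21 metal handling genes passed (median -0.02, adjusted p = 0.352), with Ctr1A at -0.27 and Tsf3 at -0.26, nor did any of 17 DNA damage and cell death genes (median 0.03, adjusted p = 0.352), with Blm at 0.16. The DNA damage and cell death list passed without Calment1/4 replicate 1 (median 0.14, adjusted p = 0.0141) and with array weights (adjusted p = 0.0465).

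The circadian clock list shifted up, with a median of 0.15 over 11 genes (adjusted p = 0.0147 preset, adjusted p = 0.657 with an estimated correlation). Pdp1 was at 0.34 and vri at 0.25, none passed, and the call was lost without CanS replicate 2 (adjusted p = 0.0680), with the mean of a gene's probe sets (adjusted p = 0.0652) and without Calment1/4 replicate 1 and CanS replicate 3 (adjusted p = 0.0741). The median was 0.10 without Calment1/4 replicate 2 and 0.25 without CanS replicate 1. The 18 neuronal markers had a median of 0.11 (adjusted p = 0.0375 preset, adjusted p = 0.657 with an estimated correlation), with VAChT at 0.27 and ChAT at 0.16. That median was 0.20 without CanS replicate 1 and 0.03 without CanS replicate 2 (adjusted p = 0.688), and the call was also lost without Calment1/4 replicate 1 (adjusted p = 0.0945) and Calment1/4 replicate 3 (adjusted p = 0.0824), after repeated quantile normalization (adjusted p = 0.0550), with the mean of a gene's probe sets (median 0.06, adjusted p = 0.139) and without Calment1/4 replicate 1 and CanS replicate 3 (adjusted p = 0.0843). Around each gene's mean, CanS replicate 1 was the highest array on the neuronal list (0.13) and CanS replicate 2 the lowest (-0.24). CanS replicate 2 was also the lowest array on the photoreceptor (-0.31) and muscle lists (-0.21). The 47 odorant-binding proteins had a median of -0.08 (adjusted p = 0.00188 preset, adjusted p = 0.657 with an estimated correlation), with Obp83cd at -0.82 and Obp83g at -0.73. Adjusted over the list alone 3 fell, and the call was lost without CanS replicate 3 (adjusted p = 0.0558). The photoreceptor (11 genes, median 0.12, adjusted p = 0.0922), muscle (16 genes, median -0.12, adjusted p = 0.157) and fat body and haemocyte lists (16 genes, median -0.27, adjusted p = 0.0922) did not pass in this comparison. The muscle median was -0.25 without CanS replicate 2 (adjusted p = 1.46e-05) and -0.20 without Calment1/4 replicate 1 (adjusted p = 0.0435). The photoreceptor median was 0.19 without CanS replicate 3 (adjusted p = 0.0367) and 0.18 without CanS replicate 1 (adjusted p = 0.0208), and that list also passed with the ovary covariate (adjusted p = 0.0482) and with the mean of a gene's probe sets (adjusted p = 0.0414). The fat body and haemocyte list passed without CanS replicate 2 (median -0.28, adjusted p = 0.0367), with the replicate block (adjusted p = 0.0206) and with array weights (adjusted p = 0.0465). Arr1 was at 0.22 and rdgC at 0.20, Mlc2 at -0.37 and Prm at -0.21, Lsp2 at -1.36 and eater at -0.64. Adjusted over the list alone 3 fat body and haemocyte genes rose and 6 fell.

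Other probe sets of the named genes had the opposite sign for Hsc70-1 (-0.03), hep (-0.04) and p53 (-0.11), none of them past the threshold.

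**Figure D2:**
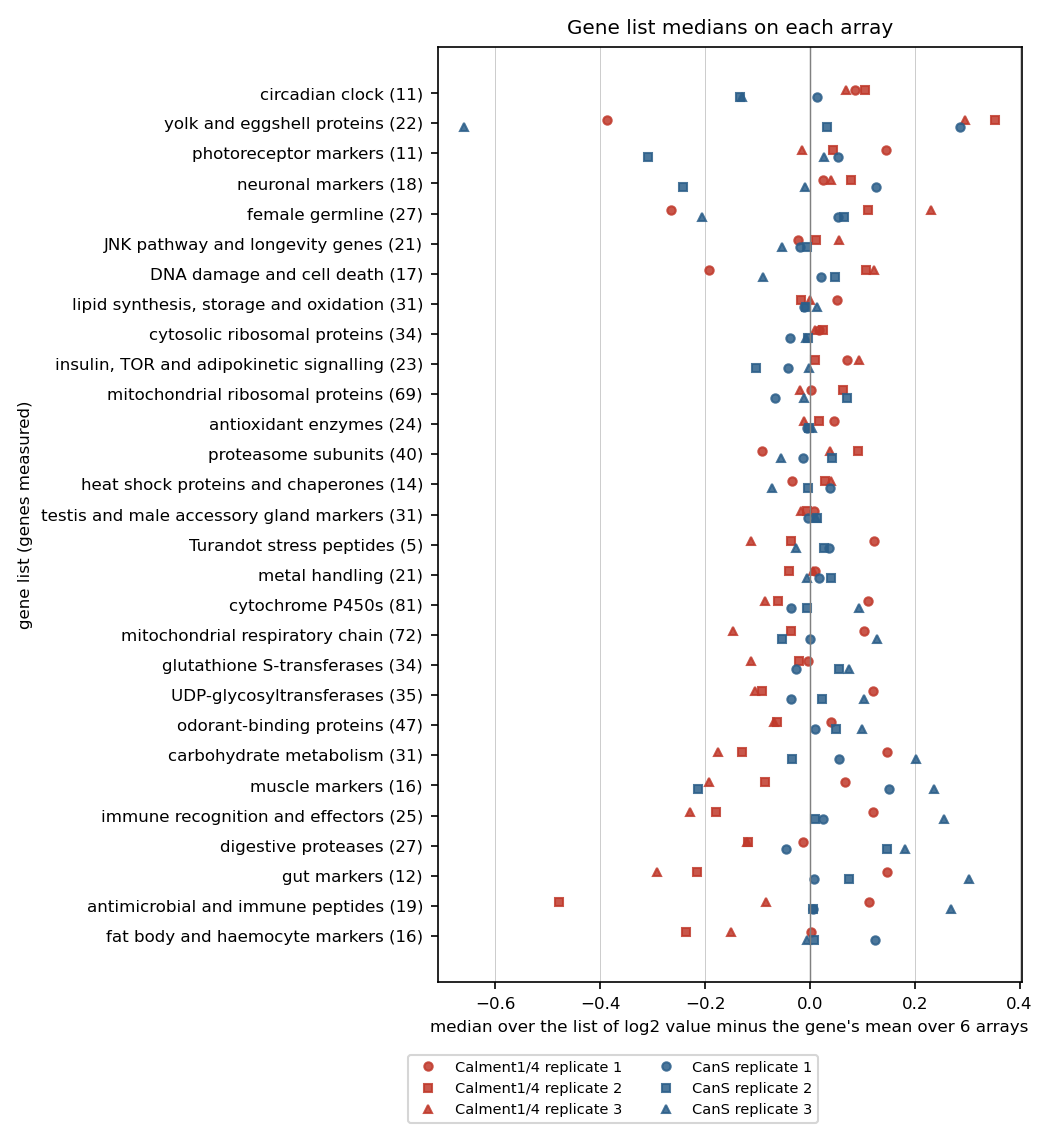
Median over each gene list of the log2 value minus the gene's mean over the 6 arrays (horizontal axis), 1 point per array, for the 29 lists with the number of genes measured, with colour for the stock and shape for the replicate. On the yolk and eggshell list Calment1/4 replicate 1 (-0.39) and CanS replicate 3 (-0.66) stand apart from their group mates.

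Changed genes were more frequent on chromosome arm 2L than elsewhere. With 1 probe set per gene, 24 of 2205 genes on 2L passed the threshold, or 1.09%, against 0.392% elsewhere (odds ratio 2.79, 95% interval 1.60 to 4.79, adjusted p = 0.00121, Fisher's exact test). They include CG3036, CG31955, lectin-24A, Cyp4d21, Ugt36A1 and Ser12. Arm 3L, which carries Arts, held 3 changed genes of 2344 (odds ratio 0.206, adjusted p = 0.00572), and 3R held 7 of 2974 (odds ratio 0.380, adjusted p = 0.0233). Arms X (14 of 1873), 2R (12 of 2428) and 4 (2 of 65) did not pass. On 2L the adjusted p was 0.0510 without Calment1/4 replicate 3, 0.368 without CanS replicate 1, 0.0583 without CanS replicate 2 and 0.0965 for at least 2-fold changes, of which 2L held 10. On 3L it was 0.412 without Calment1/4 replicate 2, 0.182 without Calment1/4 replicate 3, 0.826 without CanS replicate 1, 1 without CanS replicate 2 and 0.135 for at least 2-fold changes. On 3R it was 0.0645 without Calment1/4 replicate 1, 0.393 without CanS replicate 1, 0.152 without CanS replicate 2, 0.0583 without CanS replicate 3 and 0.334 for at least 2-fold changes. Without Calment1/4 replicate 1 arm 2R passed (62 genes, odds ratio 1.49, adjusted p = 0.0190).

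**Figure D3:**
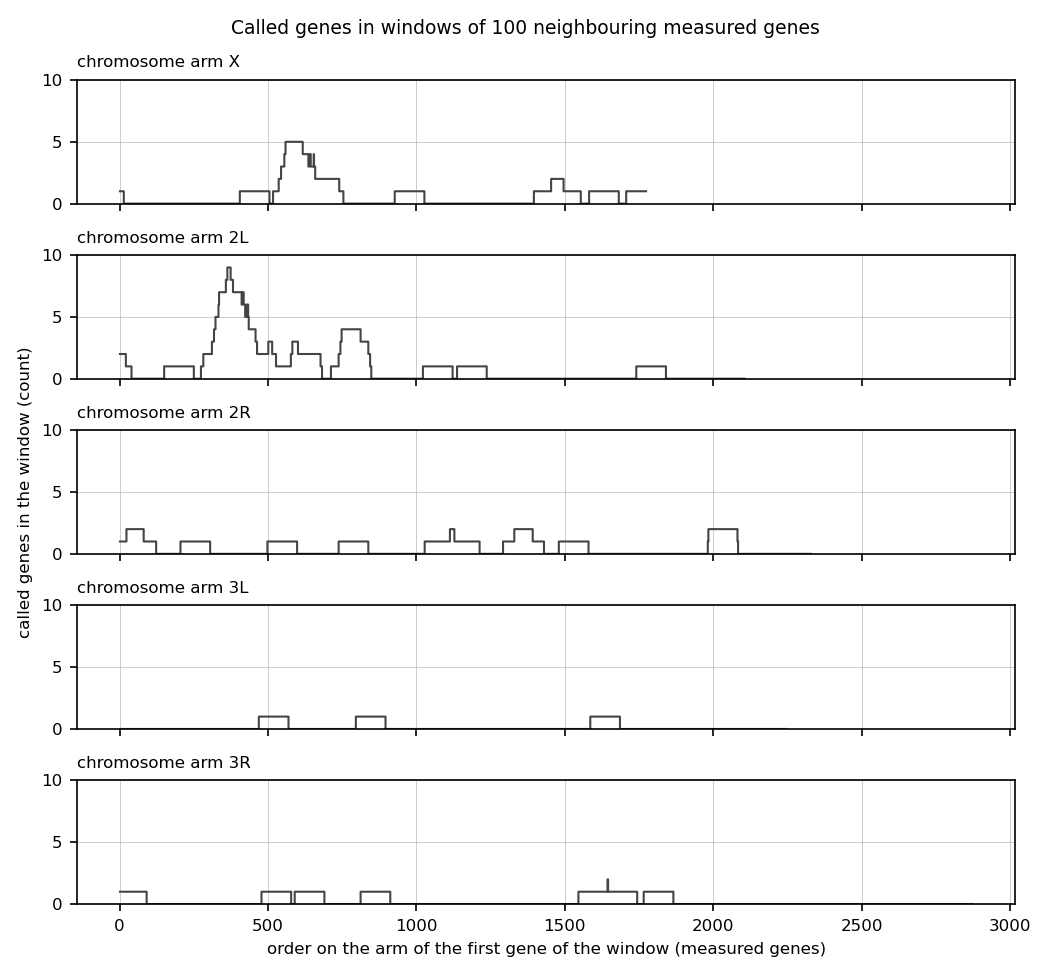
Number of genes past the threshold (vertical axis) in windows of 100 neighbouring measured genes, by the order of the window's first gene on the arm (horizontal axis), for 5 arms. The fullest window, on arm 2L, holds 9 such genes, and the fullest on X holds 5.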

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

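The ovary covariate and the setting without 2 arrays were chosen after seeing the data. The 87 calls (50 higher, 37 lower) became 337 with array weights (132 higher, 205 lower), 320 with the ovary covariate (136 and 184), 228 without Calment1/4 replicate 1 and CanS replicate 3, 38 at an adjusted p under 0.01 and 38 to 281 with 1 array left out; without Calment1/4 replicate 1 there were 84 higher and 197 lower. All 87 calls remained with array weights, with the covariate and without Calment1/4 replicate 1. The at least 2-fold count of 38 became 83 with array weights, 67 with the covariate, 96 without the 2 arrays and 31 to 94 with 1 array left out. The 10 lists became 8 after repeated quantile normalization, where the yolk and eggshell and the neuronal list lost their upward calls, 16 with array weights, 0 with an estimated correlation, 0 with fry and 7 to 15 with 1 array left out, and the yolk and eggshell median was -0.0203 to 0.442 with 1 array left out, below 0 without CanS replicate 3. The 3 arms became 0 for at least 2-fold changes and 0 to 3 with 1 array left out, and the odds ratio of 2L was 2.94 for at least 2-fold changes (adjusted p = 0.0965) and 1.58 to 3.72 with 1 array left out. Deviations of samples with equal replicate numbers correlated at -0.29, 0.20 and -0.43, which gives no sign of a pairing. These values cannot exclude a pairing, since the deviations within a group are tied to each other. Calment1/4 replicate 1 and CanS replicate 3 correlated at 0.54. With the number as a replicate block 30 calls and 0 arms were found, and 2L had an odds ratio of 2.80 (adjusted p = 0.361). Arms 3L and 3R also lost their calls with that block (adjusted p = 0.411 each), and 3R with array weights (adjusted p = 0.0998) and without the 2 arrays (adjusted p = 0.103), while X passed after centring (adjusted p = 0.0427), with trend and robust (adjusted p = 0.0266) and with the covariate (adjusted p = 0.00852). The causes of these changes were not tested. Repeated quantile normalization, centring, the filter on dim probe sets and eBayes with trend and robust on left these counts within 1.5 times. Over named genes and alternatives 916 values kept their direction and their side of the threshold, 38 newly passed, 57 no longer did and 3 changed sign, none of them past the threshold, in another probe set of hep (-0.0386), Hsc70-1 (-0.0304) and p53 (-0.11). List medians that were not past the threshold also changed sign. The testis and male accessory gland median was 0.0071 after repeated quantile normalization and 0.0042 with array weights, and that of heat shock proteins and chaperones -0.0018 with the ovary covariate and -0.0140 for the mean of a gene's probe sets. With 1 array left out, the medians ran from -0.0134 to 0.0813 for heat shock proteins and chaperones, -0.0864 to 0.0312 for Turandot peptides, -0.0296 to 0.19 for female germline, -0.12 to 0.0137 for the respiratory chain, -0.0182 to 0.0530 for mitochondrial ribosomal proteins, -0.0251 to 0.0738 for the proteasome, -0.0173 to 0.0449 for lipid genes, -0.0262 to 0.14 for DNA damage and cell death, -0.00011 to 0.19 for photoreceptor and -0.25 to 0.0280 for muscle markers. Of the 24 largest, CG43090, Arts, CG31955, Cyp6a17, y, lectin-24A, Rbm13, CG10927, CG46491, CG3036, Cyp4d21, CG12998, Ugt36A1 and Ser12 kept their calls in 14 of 14 settings, Cyp6w1 and CG30083 in 13, CG16704 and CG9664 in 11, fit and phu in 10, Sr-CI, Cpr92F and Zip102B in 9, and narya in 8. Among the other named genes, calls were lost by Prx6c, Tep3 and Cp18 with the replicate block, by Tep3 with trend and robust and by Cp18 with the filter on dim probe sets. Tep3 (adjusted p = 0.0656 in limma) and Cp18 (adjusted p = 0.0750 in limma) also lost theirs without Calment1/4 replicate 1 and CanS replicate 3. Array weights gave calls to 13 named genes and the ovary covariate to 8, AkhR, tobi, TotC, Amyrel, Jon66Ci, eater, Obp83cd and Obp83g in both. The targeted gene has no value under any setting, and the pseudocount was not run. Signal over background was not judged, so folds of dim genes stay uncertain.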

Other observations

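Chosen after their results were seen were the tests on tissue lists, also beside the maltases, on RNA integrity, on digestive proteases against maltases, on the genes with the largest changes as a check of the label, and on a mixture with CanS. The other tests were planned before, but the intervals used to read the ovary covariate and the pairs of consecutive calls were added after their values were seen.

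The maltases, enzymes that split sugars in the gut, had their lowest values in 2 of the 3 Calment1/4 arrays, replicates 2 and 3, apart from Mal-A5. For tobi, Mal-A1 and Mal-A6, Calment1/4 replicate 1 also lay below every CanS array. Over the 8 Mal-A genes and tobi the median log2 difference was -1.35 with all 6 arrays, and 0 of 9 passed in limma. Without Calment1/4 replicate 1 the median was -1.94 and 8 of 9 passed, Mal-A5 being the exception (0.16). Mal-A6 had a value of 9.32 in Calment1/4 replicate 1, 7.31 and 7.43 in the other 2 Calment1/4 arrays, and 9.44 to 10.59 in CanS. These genes lie in the carbohydrate list and were singled out after their values were seen.

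Several large differences missed the threshold. The examples here were picked after the values were seen and are not all of the largest. CG34040 was at -2.997 (adjusted p = 0.283 in limma), LManIV, an alpha-mannosidase, at -2.32, Srg2 at -2.13 and the cuticle protein gene Cpr62Bc at -1.64 (adjusted p = 0.0696 in limma). CG32751 was at 1.98 and CG40485 at 1.51, and a probe set without a symbol was at -2.46. Probe sets without a symbol reached 3.23 and -3.90 among the calls. Of 183 control probe sets 0 passed in limma and 6 had an unadjusted p under 0.05.

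A smaller share of ovary in Calment1/4 replicate 1 would raise the other tissues alike, yet its 5 other tissue lists moved apart, from -0.03 to 0.40 (permutation p = 0.000500). The shuffles treat genes as independent, while genes of a tissue can vary together within 1 array. The p therefore cannot decide whether ovary share is the whole difference, and for CanS replicate 3 it stays open too (permutation p = 0.0589). RNA degradation in these arrays would raise the 3' over 5' difference of Act5C, which was -0.17 relative to the other arrays against an SD of 0.10. For a swapped label of Calment1/4 replicate 1, the test planned beforehand came out on the side of a swap: of 94 probe sets called at least 2-fold without it, the array lay nearer the Calment1/4 mean in 44.7% (exact interval 34.4 to 55.3%) and nearer CanS in 52. That test favours a swap by construction, since leaving an array out selects genes on which it may differ, and a second test, chosen after this result, showed the array within 0.24 of its group mates for CG43090, Arts and CG3036, which a CanS sample would not be. A mixture with CanS flies is argued against too, although LManIV and CG34040, 2 of the 7 probe sets called at least 8-fold without the array, lay nearer CanS: CG3036 and an unnamed probe set, both low in the mutant, allow at most 0.447% of CanS RNA (1.56% at the upper end of their measurement spread), while the lower yolk and eggshell list would need at least 42.4% (32.9% at the end of its bootstrap interval nearest 0) and the female germline list at least 25.3% (20.3%).

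The calls on arm 2L gathered in a stretch of 309 measured genes from CG9664 to lncRNA:CR9162, which holds 14 of them, 7 higher and 7 lower. Of these, CG9664, CG3285, Sr-CIV, CG16704, Sr-CI, CG14015, CG9147 and lncRNA:CR9162 lost their calls with at least 1 array left out. The stretch was drawn to end at called genes, and it was tested only with the calls of all 6 arrays. Chance placement gave no window of 100 genes with 9 calls in 10000 shuffles (permutation p = 0.0001, the smallest they can give), and a gain or loss of the whole stretch is argued against by a median of 0.0017. A linked stretch of chromosome that differs between the stocks is a candidate explanation, as genes there that were not called also held more unadjusted p under 0.05 than elsewhere (14.2% against 8.18%, odds ratio 1.86, interval 1.30 to 2.61, Fisher's exact p = 0.000566). Of 13 pairs of consecutive calls 30.8% had one direction, which the rule set beforehand counted against shared regulation of neighbours. The exact interval, added later, was 9.09 to 61.4%, and it treats pairs that share a gene as independent. Other measured genes lie between the members of each pair, so the test cannot decide about adjacent genes, and shared regulation stays open. An effect of the mutation itself stays open and untested, since genotype and stock change together.

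For the maltases, a smaller share of gut in Calment1/4 replicates 2 and 3 would lower the digestive proteases by about as much. Without replicate 1 the digestive proteases had a median of -0.24 (bootstrap interval -0.35 to -0.07) and the maltases -1.94 (-2.29 to -1.36). The maltases were singled out for their values on these same arrays, and the intervals treat genes that vary together as independent. The comparison therefore cannot decide about gut share. A smaller share of ovary in replicate 1 would raise all other tissues alike. Its 5 other tissue lists lay -0.03 to 0.40 from the group mates with no bootstrap interval past 0.83, while the maltases lay 1.47 above (0.94 to 2.34). For the same reasons these values cannot decide about ovary share as the whole cause. With the ovary covariate the maltase median was -1.06, past the bound set beforehand, -0.97, which by that rule counted against ovary share. The bootstrap interval, -1.64 to -0.75, was added after the value was seen and holds that bound. Ovary share as a part therefore stays open. The bound came from the fall without Calment1/4 replicate 1, while the covariate fit used all 6 arrays. With all 6 arrays and no covariate the median was -1.35 and 0 of 9 maltases passed. With the covariate a smaller fall remained and 8 of 9 passed. A smaller spread left within groups can give more calls, so the number passing cannot decide about ovary share. A difference in feeding between samples may remain, and was not tested.

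The 6 arrays make 10 splits, too few for a share under 0.05. The 87 calls, 38 at least 2-fold calls and 3 arms of the real split were reached in 1 split each, the real one, with 0 the highest of the others for each. The 10 lists were reached in 5 splits and the highest other split gave 15, which parted Calment1/4 replicate 1, CanS replicate 1 and CanS replicate 3 from the rest and points to a structure of the samples.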
